A study of Homo sapiens with 8 samples.

How the data were processed

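Poly(A)-selected RNA libraries (oligo-dT beads, per the labels' protocols) were made from U87 and U251 glioblastoma cells and their NFAT5-overexpressing derivatives, with 2 libraries in each of 4 groups by the sample titles. Per the submitters' processing notes the tools were Bowtie2, RSEM and DESeq2; their versions, their settings, the genome build and the annotation are not given in the sources used here. The deposited workbook has 2 sheets. The first sets, per the file headers, NFAT5 expression against that of the line named without NFAT5, for 74 genes in each cell line. Its values were read as ratios of overexpressing over control expression. The headers and sample titles name the comparison line by cell line alone, and it is called the control here. They do not say whether it carried an empty vector. The second holds the authors' expression levels for U251, 1 column for the overexpressing and 1 for the control line, with 2 decimals and without a named unit; RSEM reports several units, and which was used is not given in the sources used here. Whether a level is a mean of the 2 libraries of a group or comes from 1 of them is also not given in the sources used here, so it is printed as the authors' value without SD or n.

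The second sheet has no gene names. Its rows were paired with the first sheet by row order, and the U251 ratio served as a check. That ratio equalled the quotient of the levels within 1e-09 in 66 of the 74 rows. In 5 of the 66 both were 0, so the ratio could not tell these rows apart. In the other 8 rows the control level was 0 and the sheet shows a division error. The ratio column of the first sheet there holds a level. It was the same as in the column of levels in 6 rows and another one in 2 rows, where the U251 values did not check the pairing. These cells were not read as ratios, and the genes were counted as higher. In U87, 7 cells of the first sheet equalled an unheaded number in the same row of the second sheet and were treated alike, as a control of 0; a quotient equals its numerator otherwise only for a control of exactly 1, and 5 of the 7 genes also have a control of 0 in U251. In all, 6 columns of the second sheet with values had no heading; they were assigned to no sample, and 2 of them were used only for these checks. U87 levels are therefore not reported, apart from printed cells of the first sheet that are read as a level. Leftover values for 3 genes under the second sheet were not used.

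Because no value could be assigned to a single library, the tests planned before the data were examined were not made. They were a linear model on log values, an exact permutation test of NFAT5 and a test of the difference between lines. With 2 libraries against 2, an exact two-sided permutation test of 1 line could not have gone below p = 0.333. The levels have no named unit, are not whole numbers and come as 1 value per group, so no count model was used. What was computed here was the number of genes higher and lower in each line, the log2 of the deposited ratios, Spearman and Pearson coefficients across genes within the higher and the lower genes, sums of levels for pairs of genes, and for each U251 ratio the lowest and highest quotient allowed by rounding each level by up to 0.005. That interval covers rounding only; the reads behind a level are unknown, and no counting interval or floor could be given. The genes named follow a rule fixed before the data were examined: in a table this short any gene may be named, NFAT5 comes first, and the 10 ratios furthest from 1 in each line are given, except that 1 gene is not reported here. Alternatives were pseudocounts of 1, 0.1 and 0.01, a level of at least 1 in 1 group, centring on the median of the table, reading each cell as printed and requiring the whole rounding interval to lie past 1.5-fold; the last 2 were chosen after seeing the data.

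Gene names were matched to a RefSeq gene table of assembly GRCh38.p14, 60 by symbol, 6 by gene number and 4 by an older symbol, so that 70 of 74 had a match; it was used only for names, gene biotypes and which genes neighbour each other, and no coordinates are printed because the authors' build is unknown. Neighbours were matched genes at most 1 Mb apart, and 10000 random lists with the same number of genes of each RefSeq biotype served as the comparison. Beforehand, the rounding intervals were tested on simulated values, and the neighbour counts and rank correlation on small constructed examples with known answers. Python 3.11.15 was used, with matplotlib 3.10.9 for the plots.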

Results

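RNA sequencing was applied to 2 human glioblastoma cell lines, U87 and U251, each as a control line and as a derivative made to overexpress NFAT5, a transcription factor best known for switching on osmoprotective genes under hypertonic stress. The labels describe 8 libraries, 2 in each of the 4 groups, and the series title places the comparison in the setting of resistance to temozolomide (TMZ), the alkylating drug used against glioblastoma. The values analysed here are the authors' ratios of overexpressing to control expression for 74 genes in each line, and for U251 also 1 expression level per group. The U87 column is headed U87/EGFR, whereas the sample labels say U87. What the added name stands for is not given in the sources used here. Titles and headers name the controls by cell line alone, without saying whether they carried an empty vector. No value could be assigned to a single library, so the ratios carry no replicate error and no test between groups could be made. Total depth is also unknown. The only error that could be computed was the rounding of the U251 levels to 2 decimals, which was used as the interval of each U251 ratio. "Higher" and "lower" therefore describe the deposited values and not a tested change.

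The first question was whether the overexpressing lines carried more NFAT5 transcript. In the authors' deposited table NFAT5 was 39.2 times the control in U87 and 18.7 times the control in U251. The U251 levels behind that ratio in the authors' deposited table were 97.36 with overexpression and 5.2 in the control, with a rounding interval of 18.70 to 18.74 for the ratio. NFAT5 had the highest level of all 74 genes in overexpressing U251, followed by TUBA1A at 73.65 in the authors' deposited table. The direction in both lines was that of the labels. The table gives 1 value per gene, so transcript from the introduced copy and from the cells' own gene was not separated.

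**Figure D1:**
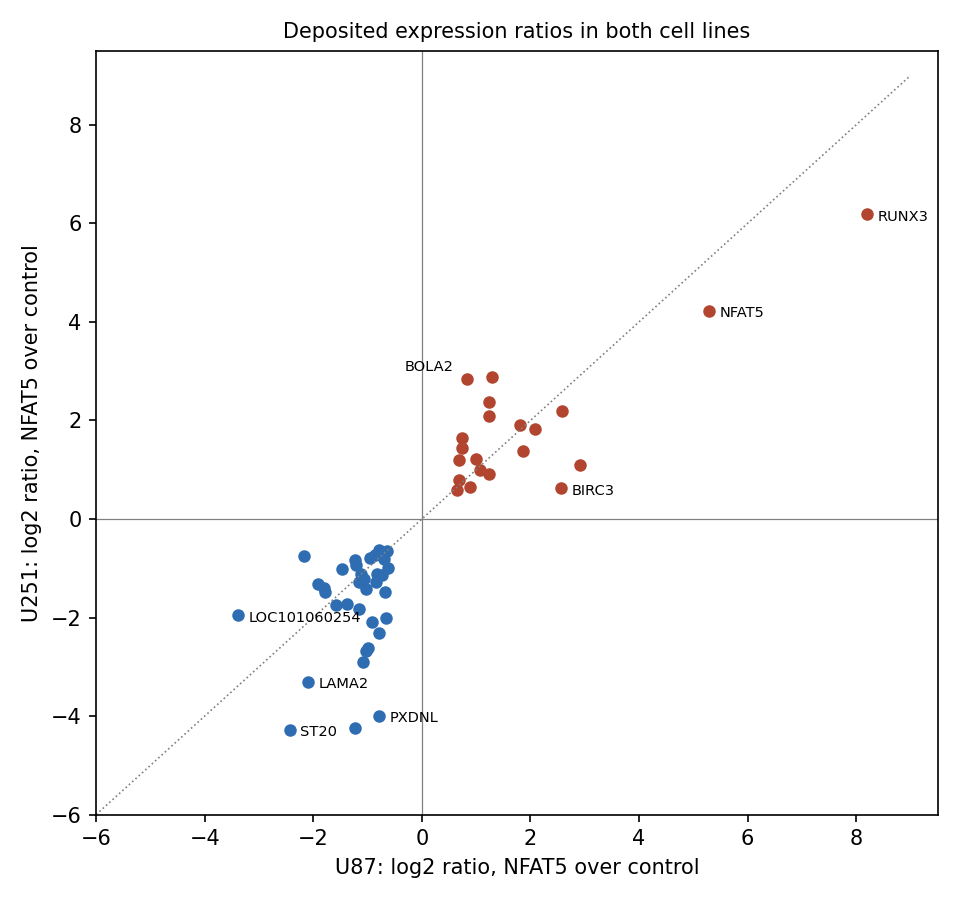
Log2 ratio of overexpressing to control expression in U87 (x axis) and U251 (y axis) for each gene with a ratio above 0 in both lines, from the authors' deposited table; each point is 1 gene, red for the 21 higher genes and blue for the 35 lower genes, and the dotted line marks equal ratios. RUNX3 and NFAT5 lie far from the other genes, with log2 ratios of 8.20 and 5.29 in U87 and 6.18 and 4.23 in U251.

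The second question was which genes differed with NFAT5 overexpression in both lines. Of the 74 genes in the authors' deposited table, 31 were higher and 43 were lower in U87, and the same 31 were higher and the same 43 lower in U251. The smallest listed differences in the authors' deposited table were a ratio of 1.56 among higher genes and 0.647 among lower genes in U87, and 1.51 and 0.651 in U251, so each listed ratio lay at least 1.5-fold from 1 in both lines. In U251, 10 genes stayed at least 1.5-fold higher and 17 at least 1.5-fold lower with a pseudocount of 1 added to the levels, and 15 and 21 did so with a level of at least 1 in either group. The rule by which the authors chose the genes is not given in the sources used here. With level cells read as higher, the list holds only genes with the same direction in both lines. Their shared direction is in part set by that reading and is not independent evidence. By the authors' annotation the list held 42 mRNAs, 29 long non-coding RNAs and 3 pseudogenes. In U251, 17 of the mRNAs, 13 of the long non-coding RNAs and 1 pseudogene were higher in the authors' deposited table.

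Among the higher genes with a ratio, RUNX3, a Runt-family transcription factor, had the largest in both lines, at 293 times the control in U87 and 72.7 times in U251 in the authors' deposited table. RUNX3 stood at a level of 0.11 in control U251 and 8 in overexpressing U251 in the authors' deposited table, and rounding alone allows a ratio of 69.5 to 76.2. No U87 levels stood in a named column, so no such interval could be given for the ratio of 293. The deposited ratio of RUNX3 exceeded that of NFAT5 in both lines. With a pseudocount of 1 added to the U251 levels the RUNX3 ratio was 8.11, against 15.9 for NFAT5. With 0.1 it was 38.6 against 18.4, and with 0.01 it was 66.8 against 18.7. The order in U251 thus reversed only with the largest pseudocount, which exceeds the control level of RUNX3. MGMT, the enzyme that removes the O6-methylguanine lesions made by temozolomide, was 1.99 times the control in U87 and 2.31 times in U251 in the authors' deposited table. Its U251 levels were 27.62 and 11.94, which made it 1 of only 7 genes that reached a level of 10 in either U251 group in the authors' deposited table. HLX, a homeobox transcription factor, had ratios of 1.60 and 1.73 in the authors' deposited table. KIAA1107 at 3.50 and 3.75, SLC34A1, a sodium-phosphate cotransporter, at 2.36 and 5.2, and KLHL23 at 1.67 and 3.13 were further higher mRNAs in the authors' deposited table.

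Several higher genes differed in the size of their ratio between the lines. BIRC3, an inhibitor of apoptosis protein of the NF-kB pathway, was 5.91 times the control in U87 and 1.54 times in U251 in the authors' deposited table. The long non-coding RNA LOC100287846 went the same way, at 7.5 and 2.14 times the control in the authors' deposited table. By contrast, LOC107986742 was 2.45 times the control in U87 and 7.40 times in U251, and the readthrough transcript ARL2-SNX15 was 2.37 and 4.26 times the control, in the authors' deposited table. These differences between lines were not tested. Among the 21 higher genes with a ratio in both lines, Spearman's rho of the log2 ratios across genes was 0.47 and Pearson's r was 0.81; without NFAT5 and RUNX3 they were 0.29 and 0.06, so Pearson's r rested on those 2 genes and rho was lower without them. Among the 35 lower genes rho and r were both 0.23. Of these 35, 23 lay further from 1 in U251 than in U87, against 10 of the 21 higher genes. Lower genes at 0 in only 1 line are not among the 35. They were LOC107986079, STT3A-AS1 and LOC729451, at 0 in U87, and LOC105378286, at 0 in U251. Genes are not independent replicates, and no p-value was attached to these coefficients.

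For 10 of the higher genes a fold could not be written in 1 line or both because the control was read as 0, for 7 in U87 and 8 in U251, with 5 genes in both. In these cells the authors' deposited table holds a level and not a ratio. In U251 the control of 0 stands in a named column, whereas in U87 it was inferred from an unheaded one. The cation channel gene TRPC7 was listed at 0 in control U251 and at 1.62 with overexpression, and had a ratio of 80 in U87, in the authors' deposited table. DHRSX, a dehydrogenase of the short-chain family, was listed at 0 in control U251 and at 1.13 with overexpression in the authors' deposited table. PDZK1, a scaffold for membrane transporters, had a ratio of 2.3 in U251, from levels of 0.23 and 0.1, and a control read as 0 in U87, in the authors' deposited table. The others were long non-coding RNAs and the pseudogene SEC22B3, and among them LOC105376217 was listed at 0 in control U251 and at 1.26 with overexpression in the authors' deposited table. For LOC100506100 the overexpressing U251 level was 6.38 in the column of levels but 0.12 in the column of ratios, and for LOC105372906 it was 0.24 and 0.12, so both levels are uncertain in the authors' deposited table.

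**Figure D2:**
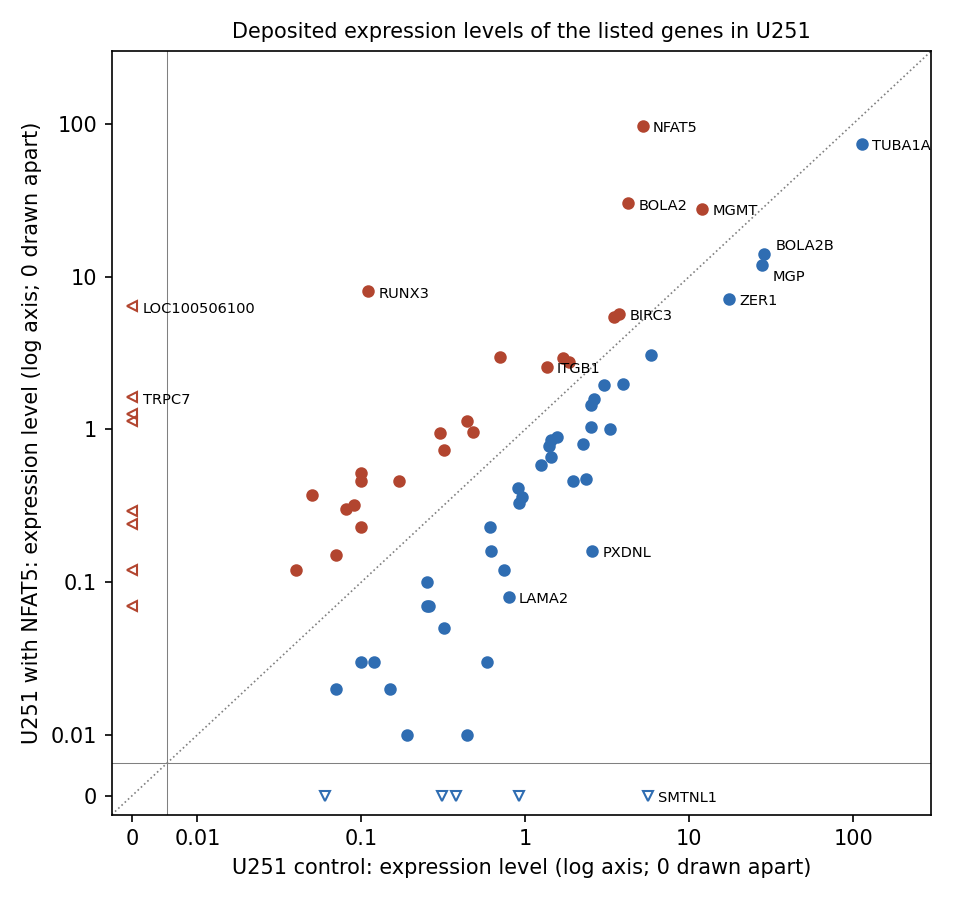
Expression level of each of the 74 listed genes in control U251 (x axis) and NFAT5-overexpressing U251 (y axis), in the authors' unnamed unit on log axes; each point is 1 gene (red higher, blue lower with overexpression), open triangles in the separated margins are genes listed at 0 in 1 of the groups, and the dotted line marks equal levels. Of the 74 genes, 38 lay under a level of 1 in both groups, and NFAT5 lay above the rest on the y axis at 97.36.

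The lower genes included a few at high levels. TUBA1A, an alpha-tubulin, was 0.576 times the control in U87 and 0.651 times in U251, from 113.18 to 73.65, in the authors' deposited table. MGP, the matrix Gla protein that restrains calcification, was 0.479 and 0.427 times the control, with U251 levels of 27.97 in the control and 11.95 with overexpression in the authors' deposited table. ZER1, a substrate receptor of a cullin ubiquitin ligase, was 0.560 and 0.409 times the control, with U251 levels of 17.37 and 7.11 in the authors' deposited table. BAALC had ratios of 0.432 and 0.521 and the histone H4 gene HIST1H4H had ratios of 0.383 and 0.303 in the authors' deposited table. GPX3, the secreted glutathione peroxidase, was 0.561 and 0.462 times the control, with U251 levels of 1.43 and 0.66, in the authors' deposited table. LAMA2, the laminin alpha-2 chain, was 0.233 times the control in U87 and 0.101 times in U251, where it went from 0.79 to 0.08, in the authors' deposited table. PXDNL, a peroxidasin-like gene, was 0.581 times the control in U87 and 0.0625 times in U251, from 2.56 to 0.16, in the authors' deposited table; this difference between lines was not tested. The lowest ratios above 0 were 0.0284 for the long non-coding RNA LOC105378286 in U87 and 0.0227 for LOC729451 in U251 in the authors' deposited table. LOC729451 went from 0.44 to 0.01 in U251 in the authors' deposited table, and rounding alone allows a ratio of 0.0112 to 0.0345. ST20 was 0.185 and 0.0517 times the control, and LOC101929231 was 0.429 and 0.0526 times, in the authors' deposited table. In U87 the pseudogene LOC101060254, at 0.0952, and LOC107985200, at 0.223, were also among the 10 ratios furthest from 1, and in U251 TBC1D10C was, at 0.133, in the authors' deposited table.

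Overexpressing cells were listed at 0 for 8 of the lower genes in 1 line or both, and for 4 of these in both lines. Those 4 were SMTNL1, a smoothelin-like muscle gene, and the long non-coding RNAs ZNF385D-AS1, LOC102723752 and LOC105375921. SMTNL1 had a level of 5.57 in control U251 in the authors' deposited table, against 0.06, 0.31 and 0.38 for the other 3. These 4 levels were assigned to their genes by row order, since ratios of 0 could not tell the rows apart. Other lower mRNAs were GPT, the alanine aminotransferase, at 0.447 and 0.28, SLC18A2, a vesicular monoamine transporter, at 0.636 and 0.25, FSCN2, a fascin, at 0.424 and 0.561, CAMK2N2, a CaM kinase II inhibitor, at 0.551 and 0.601, PNCK, a CaM kinase, at 0.288 and 0.377, and KIF26B, a kinesin family member, at 0.598 and 0.456 times the control in U87 and U251 in the authors' deposited table.

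Some listed genes share sequence with near-identical copies or overlap a neighbour, and their values are uncertain wherever reads could be assigned to either. BOLA2 was 1.79 times the control in U87 and 7.13 times in U251, whereas its copy BOLA2B was 0.359 and 0.495 times the control, in the authors' deposited table. In U251 BOLA2 went from 4.23 to 30.18 and BOLA2B from 28.42 to 14.07 in the authors' deposited table. The sum of both was 32.65 in the control and 44.25 with overexpression, a ratio of 1.36. NOTCH2NLA and NOTCH2NLC, members of the NOTCH2-related duplicated family, had ratios of 2.11 and 1.56 in U87 and 2 and 1.51 in U251 in the authors' deposited table. HLX was higher in both lines, whereas its antisense neighbour HLX-AS1 was lower, at 0.532 times the control in U87 and 0.236 times in U251 in the authors' deposited table.

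The table was compared with 15 gene lists with 263 entries in all, fixed before the data were examined. Only 4 lists had a member among the 74 genes: MGMT of 20 genes for temozolomide response and DNA repair, ITGB1 of 22 for extracellular matrix and invasion, BIRC3 of 18 for apoptosis, and NFAT5 itself of 7 in the list of NFAT5 and resistance-related non-coding RNAs. Each of these 4 was higher in both lines, but for NFAT5, the overexpressed gene, the direction was set by the design. A single member does not give the direction of its list. None of the 16 osmoprotective NFAT5 targets, such as AKR1B1 and SLC5A3, was among the 74 genes analysed here, nor was a member of the 9 drug efflux transporters, the 22 glioma stem cell and mesenchymal genes, the 20 inflammation genes, the 20 interferon genes, the 20 cell cycle genes, the 17 hypoxia genes, the 14 unfolded protein response genes, the 16 oxidative stress genes, the 22 receptor tyrosine kinase genes or the 20 markers of other cell types. Because the rule behind the list is unknown, a gene that is absent from the 74 cannot be called unchanged, and no enrichment was tested.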

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

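All tests in this part were chosen after the values had been seen. Read as ratios, the printed entries of 5 genes lay on opposite sides of 1 in U87 and U251: LOC100506100 at 5.58 and 0.12, LOC112267877 at 3 and 0.12, PDZK1 at 0.18 and 2.3, LOC101928499 at 0.05 and 3, and DHRSX at 0.49 and 1.13. The difference between the lines was not tested, since no replicate values were used. A candidate explanation is that a cell holds another unit than its column name says, a level entered where the control is 0. Of the 5 genes, 0 had 2 cells that were both quotients. With such cells read as a control at 0, 0 of the 74 listed genes had opposite directions. That count decides nothing about opposite responses of the lines, because the reading itself makes such cells higher. So read, the list also holds only genes with 1 direction. For LOC112267877 and DHRSX the reading of a level rests on the named U251 columns, which hold the printed value beside a control of 0. For LOC100506100 only the control of 0 supports it, since the named column gives 6.38 and not the printed 0.12; for PDZK1, LOC101928499 and the U87 cells of the first and last gene it rests on an unheaded column of the same workbook.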

How the results depend on the processing

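No paired analysis was possible because the deposited columns carry no replicate numbers and none could be assigned to a single library. For the same reason leaving out each replicate, a filter or trend in a fitted model, other normalizations and fits within 1 line were not run. No value is known for single libraries, so nothing below speaks to replicate error, and depth limits cannot be stated. In U251, 31 genes were at least 1.5-fold higher and 43 at least 1.5-fold lower; with a pseudocount of 1 these counts were 10 and 17, and with a level of at least 1 in 1 group they were 15 and 21. The filter leaves these numbers by construction, since 38 of the 74 genes lie under a level of 1 in both groups. Of the 47 genes that the pseudocount of 1 brought within 1.5-fold, 34 were among those 38 and 13 had a level of 1 or more in either group. With a pseudocount of 0.1 the counts were 29 and 42 and with 0.01 they were 31 and 43. Centring on the medians of the table (0.615 in the control, 0.465 with overexpression) gave 31 and 35, with a factor of 0.756. Dividing by this factor raises every ratio, so the higher count could not fall and the lower count could not rise. The medians are those of a chosen list with 43 lower and 31 higher genes. The factor therefore does not measure a shift across all genes. Read as printed, the cells gave 24 and 48 in U251 and 25 and 49 in U87, against 31 and 43 in both. Requiring the whole rounding interval to lie past 1.5-fold gave 30 and 43, and the gene lost was NOTCH2NLC, whose interval starts at 1.499. The NFAT5 ratio in U251 was 18.7 as deposited, and 15.9, 18.4 and 18.7 (18.69) with pseudocounts of 1, 0.1 and 0.01. After centring it was 24.8, a rise that the factor sets by construction. The RUNX3 ratio in U251 was 72.7 as deposited and 8.11, 38.6 and 66.8 with those pseudocounts, and only with a pseudocount of 1 was it below that of NFAT5. The as-printed and rounding alternatives were chosen after seeing the data.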

Other observations

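Long non-coding RNAs made up 29 of the 74 genes, and 7 of these carry an antisense name. In the authors' deposited table SLC25A5-AS1, at 4.23 in U87 and 3.56 in U251, and STXBP5-AS1, at 1.61 and 2.28, were higher, and LINC01619, an intergenic RNA, was also higher at 1.67 and 2.71. ELOA-AS1, at 0.624 and 0.357, LIX1L-AS1, at 0.289 and 0.359, and HLX-AS1, at 0.532 and 0.236, were lower in the authors' deposited table. STT3A-AS1 was listed at 0 in overexpressing U87 and at a ratio of 0.269 in U251. Among the mRNAs, ITGB1, a receptor chain used by most adherent cells, stood at only 1.35 in control U251 and 2.56 with overexpression, while TUBA1A stood at 113.18 and 73.65. MGMT stood at 11.94 in control U251.

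The tests below were chosen after the values had been seen. In 3 places a higher and a lower gene of the list were copies of each other or overlapped in the RefSeq table: BOLA2 with BOLA2B, HLX with HLX-AS1, and LOC100506100 with ZER1. One hypothesis is that reads were assigned to the other member of the pair in the overexpressing line. In that case the summed level may change less than either member. For any higher and lower gene, however, the ratio of the sums cannot lie outside the ratios of the members. A smaller change of the sum is therefore in part fixed by arithmetic and does not by itself speak for moved reads. The ratios of the summed U251 levels were 1.36, 0.929 and 0.777, all 3 within 1.5-fold, but 38.6 percent of all 1333 higher-lower pairs of the list also stayed within 1.5-fold, and with the other deposited level of LOC100506100 the last ratio was 0.416. BOLA2 gained a level of 25.95 while BOLA2B lost 14.35, so a transfer between them would cover only part of the gain if both are in 1 unit. Read reassignment and opposite regulation of the pair cannot be told apart, because no spread between libraries was available to set against these ratios. The unit is also unknown, and in a unit scaled by transcript length, moved reads need not leave the summed level unchanged.

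Of the 70 listed genes with a RefSeq match, 12 lay within 1 Mb of another listed gene, in 10 pairs, 7 of them with opposite directions. Random lists of the same biotypes held a median of 2 pairs. The share with 10 or more was 0.0013, computed with 1 added to the number of such lists and to the number of all lists. PDZK1, LIX1L-AS1, LOC101060254 and NOTCH2NLA alone make 6 of the listed pairs. Counted as separate neighbourhoods there were 5, and the share of random lists with as many, computed alike, was 0.0902. Whether listed genes lie closer together than random placement gives cannot be told apart on these counts, which disagree, and the genes that could have entered the list are unknown.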
